A study of Mus musculus with 16 samples.

How the data were processed

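Gene expression was measured by poly-A RNA sequencing in 16 libraries of mouse CD8 T cells enriched from spleen, 4 each from wild-type and Batf3 ko cells cultured for 48 h or 72 h. Per the labels' protocols, the culture held IL-15 at 50 ng/ml with plate-bound anti-CD3 and anti-CD28 at 1 µg/ml each, and stranded libraries were made from 100 ng of RNA. Per the submitters' processing notes, bcl2fastq 2.2.0, STAR 2.7, featureCounts and the build GRCm38 were used. The values deposited by the authors are whole-number read counts per gene, not normalized, for 55335 gene identifiers. The annotation release, the strand setting and the rule for reads with several matches are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes are uncertain. Poly-A selection and gene-level counting leave out RNA without a poly-A tail and do not separate isoforms.

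Symbols, positions and exon lengths were taken from GENCODE M21 for GRCm38, in which 55154 of the identifiers were found. Library totals ran from 29375818 to 39241169 counts, and 3 counts, the limit that a count of 0 allows, corresponded to 0.0765 to 0.102 CPM. Such limits cover counting error only. No pair of libraries in a group agreed within sampling noise.

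All 16 libraries in 4 groups, taken from the labels, entered a fit with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, robust quasi-likelihood F test, two-sided). Of the genes, 15197 were tested, and p-values were adjusted by the Benjamini-Hochberg method over them with a threshold of 0.05. Counts of genes are given at any size and for changes of at least 2-fold. The standard error of a log2 fold change was its size divided by the square root of F. The comparisons were ko against wild type at each time, 72 h against 48 h in each genotype, and the interaction of genotype and time. The median biological coefficient of variation was 9.68%.

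Of 37 gene lists fixed before the data were examined, 36 had at least 3 tested members and were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry, which tests a list against no change and not against other genes, were alternatives. Genes were named by a rule fixed at the same time. For each genotype comparison it took the 12 largest rises and 12 largest falls, for each time comparison 8 each way and for the interaction 6 each way. These were among genes past the threshold with an average log2 CPM of at least 3 and no overlap between the groups. It left out receptor and immunoglobulin segments, clone-named models and pseudogenes. Up to 4 members of each list past the threshold, and a fixed set of T cell genes whatever their result, were added.

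The alternatives were median-ratio and library-size scaling, DESeq2 1.42.0, limma-voom, other filters on low counts, a fit of only the groups compared, the replicate number as a block, a test against a 1.5-fold change and leaving out each library in turn. Added after the data were seen were a fit without the libraries that stand apart, offsets that remove each library's trend with exon length, and lists without Batf3. Counts were simulated for the 48 h comparison over 15197 genes. On them edgeR recovered 81% of 100 genes changed 1.5-fold and 91% of 100 changed 2-fold. Of its 182 calls 10 (5.49%) were unchanged genes. In DESeq2 20 of 199 calls (10.1%) were unchanged genes, and in limma-voom 11 of 181 (6.08%). The changed genes were not drawn from those of lowest expression. The simulated counts held no trend with exon length and no library that stands apart, so these rates may not hold for the real comparison.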

Results

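The data were poly-A RNA sequencing libraries from mouse CD8 T cells, the lymphocytes that kill infected cells. Cells enriched from the spleens of wild-type C57BL/6 mice and of mice lacking Batf3 (ko) were activated through the T cell receptor and CD28 with plate-bound antibodies in medium containing the cytokine IL-15. RNA was taken after 48 h or 72 h. Batf3 encodes a basic leucine zipper transcription factor of the AP-1 group. The 4 groups (wild type and ko at each time) held 4 libraries each, 16 in all, with 29375818 to 39241169 counted reads per library. The series text calls the 4 libraries of a group technical replicates, so the p-values given here measure the spread between such libraries and not between animals. The comparisons ask how loss of Batf3 changed expression at each time, how expression changed from 48 h to 72 h in each genotype, and whether the effect of the genotype differed between the times. The first principal component of 9191 expressed genes held 83.1% of the variance and the second 7.89%.

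Batf3 itself (ENSMUSG00000026630), on chromosome 1 from 191097847 to 191108945 in GRCm38, was read in every library first. It had 79.2 ± 5.58 CPM (counts scaled to a common library size; SD, n = 4) in wild-type cells at 48 h and 29.8 ± 2.58 (SD, n = 4) at 72 h. In ko cells it had 0.128 ± 0.0634 CPM (SD, n = 4) at 48 h and 0.0973 ± 0.195 CPM (SD, n = 4) at 72 h. The ko libraries held 2, 3, 7 and 6 Batf3 reads at 48 h and 0, 0, 11 and 0 at 72 h. All 16 libraries matched their genotype label in this gene. In wild-type cells Batf3 fell by 1.41 on the log2 scale from 48 h to 72 h (SE 0.14, adjusted p = 3.0e-08, edgeR quasi-likelihood test).

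**Figure D1:**
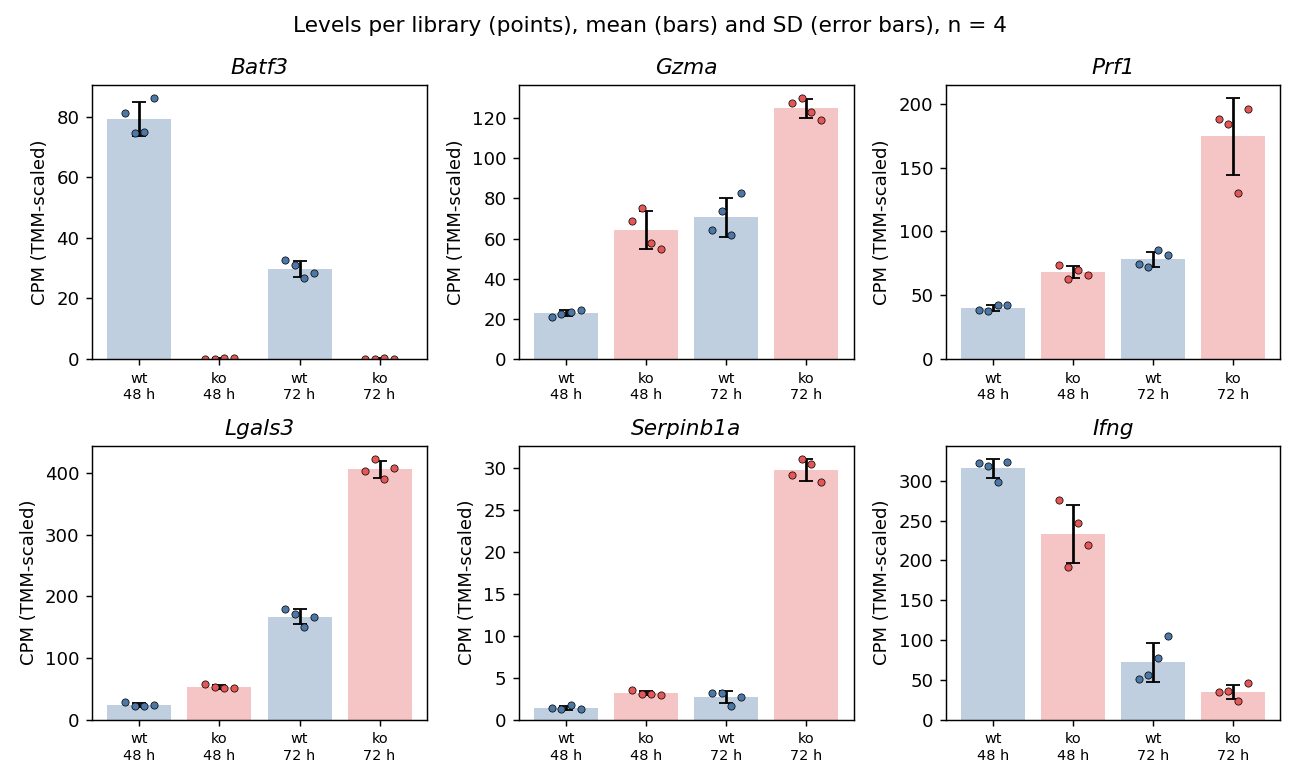
Expression of 6 genes in CPM (y axis, TMM-scaled, starting at 0) in the 4 groups (x axis); points are single libraries, bars the group means and error bars the SD of 4 libraries. Batf3 is near 0 in all ko libraries, and Gzma, Prf1 and Lgals3 are higher in ko than in wild-type libraries at both times. Serpinb1a rises from 3.17 to 29.8 CPM in ko cells between the times, and Ifng is lower at 72 h than at 48 h in both genotypes.

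At 48 h, cells without Batf3 expressed more of the genes for killing granules than wild-type cells. Gzma, which encodes the serine protease granzyme A, averaged 64.2 ± 9.51 CPM (SD, n = 4) in ko against 22.8 ± 1.5 CPM (SD, n = 4) in wild-type cells. Its log2 fold change was 1.49 (SE 0.10, adjusted p = 1.3e-10, edgeR quasi-likelihood test). Prf1, the pore-forming protein perforin, was higher by 0.76 (SE 0.10) and Gzmb, granzyme B, by 0.36 (SE 0.06) on the same scale. Il10, an immunoregulatory cytokine, was higher by 2.24 (SE 0.22) from a low level, 4.91 ± 0.505 CPM (SD, n = 4) against 1.03 ± 0.164 (SD, n = 4). Lower in ko cells were Gata3 (-0.79, SE 0.13), the master regulator of type 2 T cell responses, and the chemokine receptor Ccr8 (-0.84, SE 0.13).

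Of 21 tested cytotoxic granule genes, 10 were higher and 0 lower in ko cells at 48 h (12 and 0 when adjusted over the list alone; camera adjusted p = 4.41e-15, and adjusted p = 0.00256 with an estimated correlation). Gzmd and Gzme, at 1.11 and 1.17, were among them, but granzymes D to G are close relatives and their reads are uncertain. The effector differentiation list, which shares members with the granule list, had 9 of 23 genes higher and 0 lower (11 and 1 adjusted over the list alone; camera adjusted p = 3.45e-06, and adjusted p = 0.0147 with an estimated correlation). Prdm1, which encodes the terminal differentiation regulator Blimp-1, stood at 0.92 (SE 0.11), the chemokine Ccl5 at 0.70 and the receptor Klrd1 at 0.75 (adjusted p = 0.0575 without ko 48 h replicate 2). Natural killer (NK) and gamma delta T cell markers moved in the same libraries: 2 of 12 were higher (also 2 adjusted over the list alone), Klrb1c (1.21) and Klre1 (1.02). Their list had camera adjusted p = 0.00466 and adjusted p = 0.0409 with an estimated correlation. Of 4 tested macrophage, monocyte and granulocyte markers 2 were higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 3.49e-07, and adjusted p = 0.00256 with an estimated correlation). These were Ccr2 (0.72, SE 0.13) and Fcgr3, at 3.475 ± 0.309 CPM (SD, n = 4) in ko against 0.224 ± 0.112 CPM (SD, n = 4) in wild-type cells. That list holds 20 markers, and the others did not pass the filter on low counts, so its test rests on 4 genes. Fcgr3 lies on chromosome 1, which also carries Batf3, so sequence differences carried with the ko allele were not excluded. Of 7 tested B cell markers 1, Ighm (0.28, SE 0.06; adjusted p = 0.0581 with exon length offsets), was higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.964). Their sum was 303.1 ± 14.3 CPM (SD, n = 4) in ko against 251.5 ± 4.32 CPM (SD, n = 4) in wild-type cells, nearly all of it Ighm (295.2 and 242.8 CPM). Fold changes at 48 h also followed transcript length, with a Spearman correlation of -0.402 with exon length across 9191 genes, which are not independent replicates. With exon length offsets, added after the data were seen, 738 of the 1075 calls at 48 h stayed in the same direction (68.7%).

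Genes of the amino acid stress response driven by the transcription factor ATF4 were higher at 48 h, 7 of 22 against 0 lower (15 and 0 adjusted over the list alone; camera adjusted p = 1.62e-08, but adjusted p = 0.0584 with an estimated correlation). They included Ddit3 (0.87, SE 0.12), which encodes CHOP, and Chac1 (0.81, SE 0.10). Type 2 genes were lower as a list, with 3 of 11 lower and 1, Il10, higher (3 and 1 adjusted over the list alone; camera adjusted p = 0.0430, and adjusted p = 0.338 with an estimated correlation). Of 77 ribosomal protein genes 23 were higher and 0 lower (35 and 0 adjusted over the list alone; camera adjusted p = 1.13e-12, and adjusted p = 0.557 with an estimated correlation). With exon length offsets 22 were higher and 0 lower, and their median log2 fold change was 0.0903 against 0.172. Among 10 pro-apoptotic BCL2 family genes, 3 were higher and 0 lower (3 and 1 adjusted over the list alone). These were Bmf at 1.09 (SE 0.17), Bbc3, which encodes PUMA, at 0.35 (SE 0.08) and Bcl2l11, which encodes BIM, at 0.35 (SE 0.10, adjusted p = 0.0305). The list did not pass (camera adjusted p = 0.101). That test sets a list against the other genes; in fry, which asks whether a list differs from no change, its adjusted p was 0.00399. The Bcl2l11 call was lost in edgeR without wild-type 48 h replicate 1, 3 or 4 (adjusted p = 0.0696, 0.0984 and 0.0862). It was also lost without ko 48 h replicate 2 or 3 (adjusted p = 0.0845 and 0.0556) and with library-size scaling (adjusted p = 0.0647). The pro-survival family list did not pass (camera adjusted p = 0.659; 1 of 7 genes lower when adjusted over the list alone), with Bcl2 at 0.15 (SE 0.07) and Mcl1 at 0.13 (SE 0.05), neither past the threshold over all genes. Bcl2 passed with exon length offsets (adjusted p = 0.0232). Bcl2l1, which encodes BCL-XL, stood at -0.20 (SE 0.06) and just missed the threshold (adjusted p = 0.0561). It passed with median-ratio and library-size scaling, DESeq2, limma-voom, only the groups compared and the replicate block (adjusted p = 0.0431, 0.0356, 0.0154, 0.0478, 0.0491 and 0.0461). It also passed in edgeR without ko 48 h replicate 4, wild-type 72 h replicate 2, 3 or 4, or ko 72 h replicate 3 (highest adjusted p = 0.0446), and without both libraries that stand apart (adjusted p = 0.027). Of 26 naive and memory-associated genes 2 were higher and 2 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.386), among them Dapl1 at -0.65 (SE 0.11). Tcf7 (-0.28, SE 0.09), Il7r (0.25, SE 0.08), Eomes (0.02, SE 0.07) and Tbx21 (0.15, SE 0.07) did not pass. Tcf7 did pass in DESeq2, with no filter and with only the groups compared (adjusted p = 0.0294, 0.0028 and 0.0243). It also passed in edgeR without ko 48 h replicate 4, wild-type 72 h replicate 4 or ko 72 h replicate 3 (adjusted p = 0.0181, 0.015 and 0.0424). Il7r passed with no filter and in edgeR without ko 48 h replicate 1, ko 48 h replicate 4 or wild-type 72 h replicate 4 (adjusted p = 0.0209, 0.0209, 0.033 and 0.0472). Without both libraries that stand apart, added after the data were seen, Tcf7 and Il7r passed too (adjusted p = 0.000548 and 0.0193).

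The largest rises by the rule for named genes were Gzma, Lgals3 (galectin-3; 1.15, SE 0.08), the water channel Aqp9 (1.13), Basp1 (1.08), Ankrd13c (0.98), Ubash3b (0.98), Ifi203 (0.93), Prdm1, Casp4 (0.91), Ddit3, Chac1 and Klra7 (0.77). The largest falls by that rule were Wdfy1 (-1.30, SE 0.14), Lrig1 (-1.03), Entpd4b (-1.01), Entpd4 (-0.98), the cytokine Lif (-0.88, SE 0.17), Dennd5a (-0.86), Cemip2 (-0.85), Gata3, Usp18 (-0.77), Tex15 (-0.77), Fnip2 (-0.65) and Dapl1. Entpd4 and Entpd4b are near-identical copies and Klra7 and Ifi203 belong to multigene families, so their values are uncertain. Sequence or copy differences carried with the ko allele were not excluded for the genes in this paragraph.

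In total 670 genes were higher and 405 lower at 48 h among 15197 tested (edgeR quasi-likelihood test, adjusted p below 0.05), of which 61 and 37 changed at least 2-fold. Scaling by library size alone gave 534 higher and 572 lower, so the share of higher genes went from 62.3% to 48.3%. DESeq2 gave 794 higher and 844 lower (48.5%). Single libraries moved the counts, which were 336 and 171 without wild-type 48 h replicate 1, and 379 and 189 without replicate 2. They were 399 and 204 without ko 48 h replicate 1, 302 and 218 without replicate 2, 1059 and 896 without replicate 4 (56 lower by at least 2-fold), and 580 and 625 without ko 72 h replicate 3. Leaving out ko 48 h replicate 4 and wild-type 72 h replicate 4, the libraries that stand apart from their groups, an alternative added after the data were seen, gave 1379 and 1173.

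At 72 h the granule genes were again higher in ko cells, and genes of DNA replication and of type 2 cytokines were lower. Prf1 averaged 174.6 ± 30.02 CPM (SD, n = 4) in ko against 78.3 ± 5.94 CPM (SD, n = 4) in wild-type cells. Its log2 fold change was 1.16 (SE 0.09, adjusted p = 8.0e-09, edgeR quasi-likelihood test). The type 2 cytokine Il13 averaged 1.25 ± 0.411 CPM (SD, n = 4) against 8.17 ± 2.02 CPM (SD, n = 4), a log2 fold change of -2.70 (SE 0.20). Ifng, the cytokine interferon gamma, was lower, with a log2 fold change of -1.05 (SE 0.22). At 48 h it stood at -0.44 (SE 0.21, adjusted p = 0.251), and passed with no filter and with only the groups compared (adjusted p = 5.44e-08 and 0.00876). Serpinb1a, a protease inhibitor, had the largest rise by the rule for named genes, 3.45 (SE 0.14), from 2.704 ± 0.720 to 29.8 ± 1.28 CPM (SD, n = 4 each).

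Of the 21 granule genes 13 were higher and 0 lower at 72 h (13 and 0 adjusted over the list alone; camera adjusted p = 3.69e-07, and adjusted p = 0.0273 with an estimated correlation). They included Gzmk (1.35), Gzma (0.82) and Gzmb (0.43, SE 0.06). The effector differentiation list went both ways at 72 h, with 11 of 23 genes higher and 6 lower (the same adjusted over the list alone). Of these, 1 and 2 changed at least 2-fold. Its camera adjusted p was 0.0456, but 0.236 with an estimated correlation and 0.0604 with the replicate block. The NK and gamma delta markers had 4 of 12 higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.00345, and adjusted p = 0.0273 with an estimated correlation), with Klre1 at 1.03 and Gpr55 at 0.87. Macrophage, monocyte and granulocyte markers had 3 of 4 tested genes higher and 0 lower, Fcgr3 (3.84, SE 0.20), Ccr2 (1.07) and Cd68 (0.70; also 3 and 0 adjusted over the list alone; camera adjusted p = 1.51e-06, and adjusted p = 0.0118 with an estimated correlation). Of the 7 B cell markers 2 were higher, among them Ighm (0.43, SE 0.06), and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.250, and fry, against no change, adjusted p = 0.0110). Their sum was 342.9 ± 15.4 CPM (SD, n = 4) in ko against 256.2 ± 26.9 CPM (SD, n = 4) in wild-type cells, again nearly all Ighm (331.7 and 246.1 CPM). Cd8a, which encodes a chain of the CD8 co-receptor, stood at -0.05 (SE 0.05), and at -0.173 with library-size scaling, where it passed (adjusted p = 0.0129). Fold changes at 72 h had a Spearman correlation of -0.350 with exon length across the 9191 genes. Of 77 ribosomal protein genes 70 were higher and 0 lower (72 and 1 adjusted over the list alone; camera adjusted p = 6.48e-25, and adjusted p = 0.236 with an estimated correlation). With exon length offsets 60 were higher and 1 lower, and their median was 0.318 against 0.414. Their share of counts was 15.8% ± 0.383 (SD, n = 4) in ko and 13.0% ± 0.578 (SD, n = 4) in wild-type cells.

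Of 28 S phase and replication genes 22 were lower and 0 higher in ko cells at 72 h (24 and 0 adjusted over the list alone; adjusted p = 5.39e-12, and adjusted p = 0.0252 with an estimated correlation). The largest falls among them were in Orc1 (-0.85, SE 0.08), a subunit of the origin recognition complex, Cdc6 (-0.80), Rrm2 (-0.73), a subunit of ribonucleotide reductase, and Pole (-0.61). Of 28 G2 and mitosis genes 19 were lower and 1, Cenpa at 0.60, was higher (22 and 1 adjusted over the list alone; camera adjusted p = 2.27e-06, but adjusted p = 0.175 with an estimated correlation). Of 23 cholesterol synthesis genes 11 were lower and 0 higher (13 and 0 adjusted over the list alone; camera adjusted p = 7.96e-05, but adjusted p = 0.236 with an estimated correlation). Hypoxia response genes were higher, 8 of 17 against 0 (8 and 0 adjusted over the list alone; camera adjusted p = 0.000104, but adjusted p = 0.275 with an estimated correlation), with Bnip3l at 0.67 and Ndrg1 at 0.61.

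Of 11 type 2 genes 7 were lower and 1 higher at 72 h (8 and 1 adjusted over the list alone; median log2 fold change -1.26, camera adjusted p = 7.36e-06, and adjusted p = 0.0252 with an estimated correlation). Ccr8 stood at -2.77 (SE 0.16), Il13 at -2.70 and Il3 at -1.28, and Il10 was the member that was higher, at 2.78 (SE 0.23). Csf2, which encodes the growth factor GM-CSF, was lower at -2.09 (SE 0.21). Some genes of transcription factors were lower, Egr3 at -1.54 (SE 0.15), Egr2 at -1.39 and Nr4a3 at -1.38 (SE 0.07). The TCR signalling list did not pass (5 of 30 higher, 13 lower, and 8 and 13 adjusted over the list alone; camera adjusted p = 0.105; fry, against no change, adjusted p = 0.00718). Among the BCL2 family, Bcl2l11 was higher at 0.31 (SE 0.09, adjusted p = 0.0126), Bbc3 at 0.45 and Pmaip1, which encodes NOXA, at 0.47, while Bid was lower at -0.40. Of the pro-survival genes Bcl2l1 was lower at -0.45 (SE 0.07) and Mcl1 higher at 0.20 (SE 0.05). With library-size scaling the calls of Bcl2l11 and Mcl1 at 72 h were lost (edgeR adjusted p = 0.159 and 0.265). Neither BCL2 family list passed (3 higher and 1 lower of 10, 1 and 1 of 7, with the same counts adjusted over the list alone; camera adjusted p = 0.436 and 0.654; fry, against no change, adjusted p = 0.0333 for the pro-apoptotic list). With exon length offsets 2 of the pro-survival genes were higher and 3 lower. Of 26 naive and memory-associated genes 6 were higher, among them Bcl6 (1.30, SE 0.24) and Klf2 (0.77). Lower were 8, among them Tcf7 (-0.37, SE 0.09) and Eomes (-0.46, SE 0.07), and the list did not pass (6 and 10 adjusted over the list alone; camera adjusted p = 0.840). Batf, a relative of Batf3, was higher at both times, by 0.26 (SE 0.06; adjusted p = 0.0873 with exon length offsets, added after the data were seen) and 0.37 (SE 0.06); Irf4 was lower at 72 h (-0.36, SE 0.08). At 48 h it stood at -0.23 (SE 0.08, adjusted p = 0.0677). There it passed with median-ratio scaling, DESeq2 and no filter (adjusted p = 0.048, 0.0256 and 0.0174), in edgeR without ko 48 h replicate 4 or ko 72 h replicate 3 (adjusted p = 0.00339 and 0.0445), and without both libraries that stand apart (adjusted p = 0.00098). The AP-1, BATF and IRF list of 17 genes was lower in its test at both times. At 48 h 3 of its genes were higher and 1 lower (5 and 4 adjusted over the list alone; camera adjusted p = 4.82e-06, and adjusted p = 0.0484 with an estimated correlation). At 72 h 3 were higher and 5 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.00482, but adjusted p = 0.236 with an estimated correlation). With exon length offsets 1 was higher and 1 lower at 48 h. Its median at 48 h was 0.01 and its mean -0.51, because it contains Batf3. Without Batf3, an alternative added after the data were seen, its adjusted p was 0.628 and 0.851.

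Other genes with the largest rises at 72 h by that rule were the surface protein Cd7 (2.50, SE 0.14), the integrin Itga7 (1.83) and Cd24a (1.69, SE 0.32). They were followed by the heat shock genes Hspa1a (1.68, SE 0.40) and Hspa1b (1.64), which are near-identical copies with uncertain reads (adjusted p = 0.0579 and 0.0549 in a fit of only the groups compared). Next came the cytokine signalling inhibitor Socs3 (1.45), Fam241a (1.42), Endou (1.39), Lgals3 (1.28, SE 0.07), Sdcbp2 (1.27) and Ifi214 (1.22). The largest falls by that rule were Ccdc184 (-1.69), Egr3, Nrgn (-1.43), Nr4a3, Cemip2 (-1.36), Ccr4 (-1.26), the chemokine Xcl1 (-1.19), Epas1 (-1.13), Lad1 (-1.12), Nr4a2 (-1.07), Ifng and St3gal1 (-1.01).

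**Figure D2:**
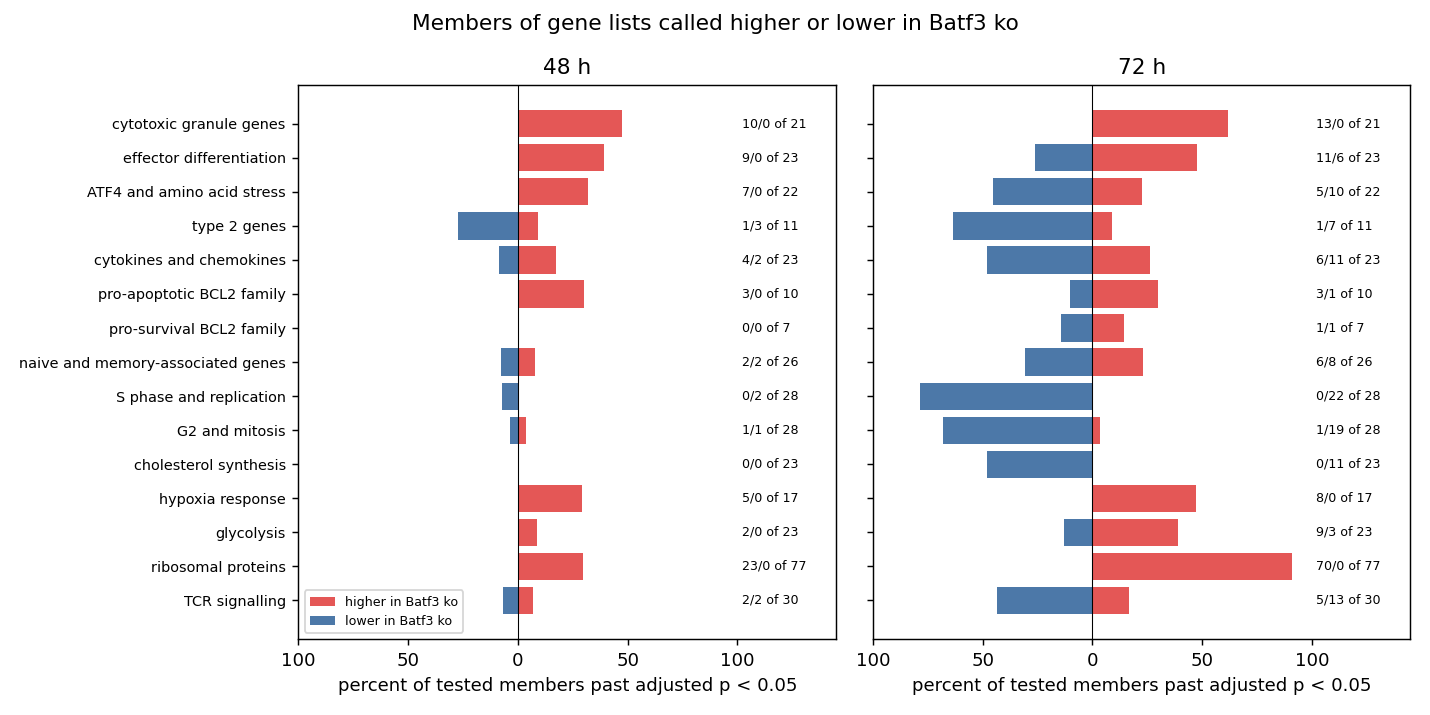
Percent of the tested members of 15 gene lists (x axis) called higher (right) or lower (left) in Batf3 ko than in wild-type cells at 48 h and at 72 h, with the counts printed beside the bars. Cytotoxic granule genes go 10 and 13 higher with 0 lower, and S phase genes go from 2 lower at 48 h to 22 lower at 72 h.

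In total 2565 genes were higher and 2961 lower in ko cells at 72 h (edgeR quasi-likelihood test, adjusted p below 0.05), 244 and 176 of them by at least 2-fold. Scaling by library size alone moved the median of all genes by -0.127 on the log2 scale and gave 1464 higher and 4779 lower, 23.5% higher against 46.4%. Without the libraries that stand apart there were 2925 higher and 3365 lower.

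The genotype effects at the separate times overlapped. These comparisons share no library, but the labels do not say whether the cells of both times came from separate mice. A difference between animals, or sequence differences carried with the ko allele, could recur at both times and give such an overlap. Both comparisons also followed exon length (Spearman -0.402 at 48 h and -0.350 at 72 h), which can add to it. The overlap with exon length offsets was not tested. Of the genes called at 48 h, 488 were also higher at 72 h, against 113.1 for independent lists, and 323 were also lower, against 78.91, while 8 went opposite ways. Gzma, Prf1, Lgals3, Ddit3 and Il10 were higher at both times, and Cemip2, Gata3, Ccr8 and Nr4a3 were lower at both. The log2 fold changes correlated across 9284 expressed genes (Pearson 0.718, Spearman 0.642; genes are not independent replicates).

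**Figure D3:**
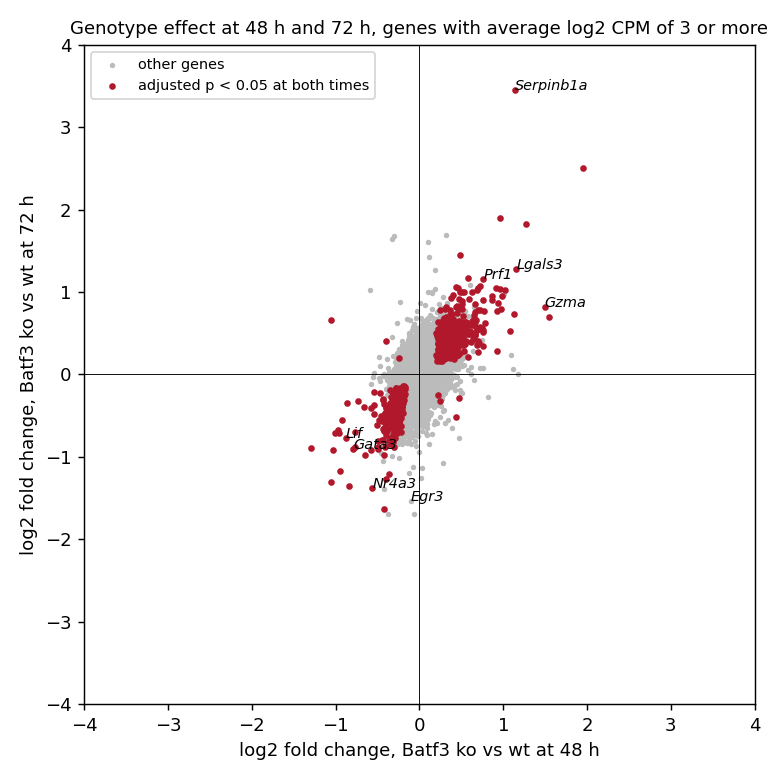
Log2 fold change of Batf3 ko against wild-type cells at 48 h (x axis) and 72 h (y axis) for genes with an average log2 CPM of at least 3, Batf3 left out. Red points passed adjusted p below 0.05 at both times, and 1 gene lies outside the axes. Most red points lie in the upper right or lower left, and Serpinb1a stands at 3.45 at 72 h.

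The effect of the genotype differed between the times for 853 genes. These were 316 with a more positive effect at 72 h and 537 with a more negative one (edgeR quasi-likelihood test of the interaction, adjusted p below 0.05), 28 and 41 of them by at least 2-fold. The type 2 genes Il13 (-2.62, SE 0.27) and Ccr8 (-1.93, SE 0.21), and Csf2 (-1.90, SE 0.28), had a more negative effect at 72 h. So did the type 2 list (4 of 11, also 4 adjusted over the list alone; camera adjusted p = 3.83e-06, and adjusted p = 0.0400 with an estimated correlation). S phase genes did too, 13 of 28 with 0 the other way (22 and 0 adjusted over the list alone; camera adjusted p = 6.67e-14, and adjusted p = 0.0309 with an estimated correlation). Orc1 stood at -0.64 and Cdc6 at -0.67. For ATF4 genes 12 of 22 had a more negative effect and 1, Nupr1 at 0.58, a more positive one (16 and 1 adjusted over the list alone; camera adjusted p = 6.24e-08, but adjusted p = 0.158 with an estimated correlation). The Nupr1 call was lost without wild-type 48 h replicate 4, ko 48 h replicate 3 or wild-type 72 h replicate 3 (edgeR adjusted p = 0.0576, 0.0553 and 0.0546). Chac1 stood at -1.08 (SE 0.15). Between the genotypes at 72 h alone, 5 of the 22 ATF4 genes were higher and 10 lower in ko cells (6 and 12 adjusted over the list alone). The ATF4 list did not pass there (camera adjusted p = 0.554). Granule genes went both ways, 2 more positive and 4 more negative of 21 (3 and 5 adjusted over the list alone; camera adjusted p = 0.900), Gzma being at -0.67 (SE 0.13). By the rule for named genes the largest positive differences included Fam241a (1.31, SE 0.15), the metallothionein Mt1 (1.11), Sdcbp2 (1.08), Socs3 (0.96) and Gpr55 (0.86), and the largest negative ones Slc2a6 (-1.62), Egr3 (-1.43), Nr4a2 (-1.35), Ccdc184 (-1.32), Penk (-1.27) and Epas1 (-1.16). Library-size scaling gave 183 positive and 1231 negative genes, 12.9% positive against 37.0%. The counts were 193 and 325 without wild-type 48 h replicate 1, and 177 and 311 without replicate 4. They were 172 and 302 without ko 48 h replicate 3, and 158 and 288 without wild-type 72 h replicate 3. They were 209 and 456 without ko 72 h replicate 1 and 281 and 233 without replicate 3. Without ko 48 h replicate 4 the 2-fold counts were 45 and 40.

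From 48 h to 72 h in wild-type cells the lists of hypoxia response and cytotoxic granule genes rose and that of S phase genes fell, but no list passed with an estimated correlation. Ifng fell by 2.13 on the log2 scale (SE 0.22, adjusted p = 1.2e-06, edgeR quasi-likelihood test). It went from 315.8 ± 12 CPM (SD, n = 4) to 72.4 ± 24.3 (SD, n = 4). The cytokines Lta and Lif fell by 3.18 (SE 0.14) and 2.94 (SE 0.18). Aldoc, a glycolytic aldolase, rose by 3.87 (SE 0.10), Il7r by 1.87 (SE 0.09), and Bcl2l11 by 1.45 (SE 0.10). Hypoxia response genes rose, 16 of 17 with 0 lower (16 and 0 adjusted over the list alone; camera adjusted p = 1.24e-14, but adjusted p = 0.0872 with an estimated correlation). Granule genes rose, 14 of 21 with 4 lower (14 and 4 adjusted over the list alone; camera adjusted p = 4.13e-06, but adjusted p = 0.0872 with an estimated correlation). S phase genes fell, 22 of 28 with 1 higher (22 and 1 adjusted over the list alone; camera adjusted p = 4.13e-06, but adjusted p = 0.0872 with an estimated correlation). By the rule for named genes the largest rises included Hspa1a (4.92, SE 0.54), Hspa1b (4.45), Aldoc, Pygl (3.86), Selenbp1 (3.81), Dapk2 (3.51) and Gsn (3.35). The largest falls by that rule were Lta, Lif, Iigp1 (-2.75), Srm (-2.35), Plaur (-2.30), Ifng, Myo19 (-2.05) and Grwd1 (-2.03). In total 5113 genes were higher and 4551 lower at 72 h, 1788 and 871 by at least 2-fold (edgeR quasi-likelihood test, adjusted p below 0.05).

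Cells without Batf3 changed most of the same genes over time. In them 5227 genes were higher and 5107 lower at 72 h, 1958 and 1370 by at least 2-fold (edgeR quasi-likelihood test, adjusted p below 0.05). Of these, 4313 were also higher in wild-type cells, against 1759 for independent lists, and 4095 also lower, against 1529, with 47 in opposite directions (Pearson 0.953 across 9284 expressed genes). S phase genes fell, 27 of 28 with 0 higher (27 and 0 adjusted over the list alone; camera adjusted p = 3.93e-11, but adjusted p = 0.0661 with an estimated correlation), and Orc1 fell by 1.94 (SE 0.07). ATF4 genes fell, 17 of 22 with 5 higher (17 and 5 adjusted over the list alone; camera adjusted p = 0.000805, but adjusted p = 0.262 with an estimated correlation). The largest rises by the rule for named genes included Hspa1a (6.90, SE 0.57), Hspa1b (6.42), the metallothionein Mt2 (4.30), Pygl (3.96), Adssl1 (3.88), Selenbp1 (3.84) and Acvrl1 (3.80). The largest falls by that rule were Lta (-3.53), Plaur (-3.03), Iigp1 (-3.00), Lif (-2.83), Ifng (-2.74, SE 0.23), Srm (-2.65), Lad1 (-2.53) and Nefh (-2.46).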

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

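The splits of the libraries were planned before the results were seen, and only the look at which libraries the draws for the interaction placed together was added afterwards.

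Among 76 groups of 4 libraries checked for a single library far from the other 3, 8 had one, and chance gives about 1 in 20. Replicate 4 of the ko cells at 48 h had 441 CPM of Xist, the RNA of the inactive X chromosome, against 129 to 181 CPM in the other ko libraries at 48 h. It had 37.2 CPM of Malat1, a nuclear RNA, against 7.40 to 9.34 CPM. Replicate 3 of the ko cells at 72 h had 16.4% of its counts in ribosomal protein genes against 15.6% to 15.7%, and 0.389 CPM of Batf3 against 0 in the other libraries of its group. Lgals3 stood apart in replicate 1 of the wild type at 48 h (28.7 CPM against 22.2 to 23.2) and in replicate 1 of the ko at 48 h (58.3 CPM against 51.8 to 52.4). In the same ko library Cd7 was at 0.696 CPM against 0.527 to 0.550. Nr4a3 was at 50.3 CPM in replicate 4 of the ko at 72 h against 43.4 to 44.5.

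For 45 of the genes named in the text the effect of the genotype differed between 48 h and 72 h, as the test of the interaction showed. The log2 difference, the effect at 72 h minus that at 48 h, was positive for Serpinb1a 2.32, Mt2 1.62, Fam241a 1.31, Mt1 1.11, Sdcbp2 1.08, Socs3 0.96, Ifit1 0.96, Nt5e 0.89, Gpr55 0.86, Cxcr6 0.85, Rgs2 0.78, Nupr1 0.58, Pgk1 0.50, Aldoa 0.42 and Cenpa 0.32. It was negative for Il13 -2.62, Ccr8 -1.93, Csf2 -1.90, Nrgn -1.83, Slc2a6 -1.62, Egr3 -1.43. Smaller negative differences were found for Nr4a2 -1.35, Ccdc184 -1.32, Il3 -1.28, Penk -1.27, Gzme -1.17, Epas1 -1.16, Chac1 -1.08, Xcl1 -1.07, Gzmd -1.05, Lad1 -1.03, Ccr4 -0.86, Bmf -0.85, Nr4a3 -0.81, St3gal1 -0.77, Cdc6 -0.67, Gzma -0.67, Orc1 -0.64, Prdm1 -0.64, Rrm2 -0.58, Basp1 -0.55, Cemip2 -0.51, Nefh -0.51, Il7r -0.48 and Eomes -0.47. Some of these calls were lost in edgeR when 1 library was left out. This held for Bmf without wild-type 48 h replicate 2 or 3, wild-type 72 h replicate 1 or 2 or 3, ko 72 h replicate 2 or 3 (highest adjusted p = 0.0695). It held for Ifit1 without wild-type 48 h replicate 2 or 3, ko 48 h replicate 3 or 4, wild-type 72 h replicate 3, ko 72 h replicate 3 or 4 (highest adjusted p = 0.0854). It held for Nt5e without wild-type 48 h replicate 1 or 4, ko 48 h replicate 3, wild-type 72 h replicate 3 or 4, ko 72 h replicate 1 or 2 (highest adjusted p = 0.0843). It also held for Il3 without ko 72 h replicate 3 (highest adjusted p = 0.0541), Il7r without ko 48 h replicate 2 (highest adjusted p = 0.0567), Nupr1 without wild-type 48 h replicate 4, ko 48 h replicate 3, wild-type 72 h replicate 3 (highest adjusted p = 0.0576).

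In the comparison of genotypes at 48 h, fitted on its 8 libraries alone, 1 of the 35 splits into 4 and 4, the real one, reached the real number of 1131 genes. The highest other split gave 0. Each other split mixes libraries of the compared groups, which widens the spread within its groups and lowers its count. Ranking first among 35 splits is the most that this test can show, so by itself it does not exclude chance in how these technical replicates fell into groups. A difference between cultures or animals would give the same and is not excluded. The same held at 72 h (1 of 35, 5193 genes, highest other 0), for time in wild-type cells (1 of 35, 9679, highest other 0) and for time in ko cells (1 of 35, 9851, highest other 0). For the interaction 2 of 100 draws of the 16 libraries, the real one included, gave at least 853 genes. The highest other draw gave 8850, several times the real count, which points to a structure of the samples. In that draw 7 of the 8 libraries on one side of the interaction were from 48 h, against 2 to 6 in the other random draws, which all gave 0 genes.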

How the results depend on the processing

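The fits without the libraries that stand apart, with exon length offsets and of lists without Batf3 were chosen after the data were seen. Across 266 pairs of a named gene and a comparison, all kept direction and side of the threshold with the stricter filter, 265 with the replicate block, 264 with limma-voom and 263 with median-ratio scaling. There were 261 with DESeq2, 260 with no filter, 258 with exon length offsets and without the libraries that stand apart, 256 with library-size scaling and 222 of 228 with only the groups compared. The test against a 1.5-fold change ended 109 calls. Most of the 266 pairs were named because they had passed, many with large changes, so they say little about the calls at large. Over all calls, the replicate block kept 882 of 1075 at 48 h (82%) and 5297 of 5526 at 72 h (95.9%). For the interaction it kept 677 of 853 (79.4%). In 4256 values from fits that each left out 1 library, 62 calls were lost and 10 values changed sign. Where a count below moved because fewer genes were tested or a larger change was required, the setting explains it; otherwise the cause was not tested.

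Library-size scaling gave 1464 higher and 4779 lower genes at 72 h and 183 and 1231 for the interaction (72 lower by at least 2-fold). DESeq2 gave 844 lower genes at 48 h and 569 positive ones for the interaction. The stricter filter gave 138 and 91 genes of at least 2-fold at 72 h, and no filter 49 and 67 for the interaction. The test against a 1.5-fold change gave 21 higher and 28 lower genes at 48 h (19 higher by at least 2-fold), 90 and 64 at 72 h (77 and 56). It gave 1957 and 1364 for time in wild-type cells, 2293 and 2022 in ko cells, and 5 and 10 for the interaction (5 and 10). Without both libraries that stand apart there were 1379 and 1173 genes at 48 h (66 lower by at least 2-fold) and 45 positive ones of at least 2-fold for the interaction.

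Leaving out each library in turn gave 302 to 1059 higher and 171 to 896 lower genes at 48 h (31 to 56 lower by at least 2-fold). It gave 158 to 407 and 233 to 649 for the interaction (18 to 45 positive by at least 2-fold). With an estimated correlation 4 lists were higher at 48 h, 3 higher and 3 lower at 72 h, 0 and 0 for time in either genotype, and 0 and 2 for the interaction. With fry 15 and 10 lists passed at 72 h, 23 and 8 for time in wild-type cells, 23 higher in ko cells and 0 positive for the interaction. Among genes changed at least 2-fold, 56 went the same way in both genotype comparisons and 2166 in both time comparisons.

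Signs of single genes changed where the main value had not passed. At 48 h Eomes stood at -0.0169 with library-size scaling, -0.00122 with DESeq2 and -0.0284 without the libraries that stand apart (-0.0287 to 0.0477 leaving out 1 library). At 48 h Cd8a stood at -0.0110 with median-ratio scaling, -0.0308 with library-size scaling, -0.0133 with DESeq2, -0.00166 with no filter and -0.0102 with length offsets (-0.0361 to 0.0315 leaving out 1 library). At 72 h Bcl2 stood at 0.0522 with length offsets. The Batf3 interaction was -0.513 in limma-voom (-3.76 to 1.29 leaving out 1 library). Of lists that had passed, without Batf3 the AP-1 list turned at 48 h (adjusted p = 0.628) and the dendritic cell list at both times (adjusted p = 0.282 and 0.372), because Batf3 had set their direction. The granule list, which had not passed, turned for the interaction with fry (adjusted p = 0.831).

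The replicate numbers do not pair the samples: 9 of 24 same-numbered pairs correlated above 0.1 (range -0.599 to 0.294), and 2 of 16 libraries correlated best with their own number. With the replicate number as a block 572 genes were higher and 346 lower at 48 h. Depth was similar across libraries and limits the low genes, such as Batf3 in ko cells.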

Other observations

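The tests of chromosome position, shared reads, transcript length, libraries that stand apart and NK or gamma delta T cells in this part were all chosen after the results were seen, as was the choice of genes named by position.

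Lists of receptor and metabolic genes held genes that went both ways between the genotypes at 72 h. Of 25 chemokine receptor and adhesion genes 10 were higher and 3 lower in ko cells (10 and 3 adjusted over the list alone; camera adjusted p = 0.265; fry, which tests a list against no change, adjusted p = 0.0211). Cxcr6, a receptor of tissue-resident cells, stood at 1.00 (SE 0.09) and Ccr4 at -1.26 (SE 0.10). Of 13 tissue-residency genes 6 were higher and 1, Xcl1, lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.0400, but adjusted p = 0.236 with an estimated correlation), among them Rgs2 at 0.84. Of 23 glycolysis genes 9 were higher and 3 lower (10 and 3 adjusted over the list alone; camera adjusted p = 0.0143, but adjusted p = 0.399 with an estimated correlation). Pgk1 stood at 0.46, Aldoa at 0.44 and the hexokinase Hk2 at -0.56.

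A list of inhibitory receptors and other exhaustion-associated genes held members that went both ways. At 48 h 5 of 18 inhibitory receptor and exhaustion-associated genes were higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.0809; fry adjusted p = 0.0238). Havcr2, which encodes TIM-3, stood at 0.76 (SE 0.11) and Lag3 at 0.46 (SE 0.09). At 72 h 6 were higher and 6 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.372; fry adjusted p = 0.0194). The 6 lower ones encode transcription factors, Nr4a3 (-1.38) and Egr2 (-1.39) among them, and not cell-surface receptors. Of 28 interferon-stimulated genes 5 were higher and 8 lower at 72 h (also 5 and 8 adjusted over the list alone; camera adjusted p = 0.817), Ifit1 being at 0.99 and Mx1 at -0.81. The dendritic cell list passed as lower (adjusted p = 2.10e-14 at 48 h and 0.000790 at 72 h, and adjusted p = 9.82e-05 and 0.0252 with an estimated correlation). Its medians were 0.12 and 0.17, and the direction came from Batf3, a member. Without Batf3 its adjusted p was 0.282 and 0.372.

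Genes that differed at least 2-fold between the genotypes in the same direction at both times lay together on chromosomes. Genes with another such gene within 0.5 Mb lay on chromosomes 1 (4 genes), 11 (6 genes), and 6, 10, 14 and Y (2 each). Those on Y were Mid1-ps1 and Gm47283, the latter at 141 CPM in wild-type cells at 48 h. However, Ddx3y, Uty, Kdm5d and Eif2s3y, which lie on Y, together had at most 1 count in any library. Reads counted on Y are therefore uncertain and do not show a block there. Mid1 on chromosome X was lower in ko cells too (-1.83 at 48 h, -1.24 at 72 h). The run on chromosome 1, which also carries Batf3, spanned 173776529 to 174031810. In it Ifi203-ps and Ifi202b were higher and Ifi211 and Ifi205 lower in ko cells. Fcgr3, at 171051174 on the same chromosome, had no such neighbour. On chromosome 11, from Cygb at 116645595 to the end of Mxra7 at 116828046 (GRCm38), 6 such neighbours were lower in ko cells. BC018473 had 6970 counts in the wild-type and 0 in the ko libraries at 48 h (at least 2202-fold lower, against a floor of 3 counts over the group) and St6galnac2, a sialyltransferase gene, 1191 and 36 counts. Of 55 such genes 18 had another within 0.5 Mb, above the highest of 10000 random sets (15, median 2). Sequence or copy differences carried in chromosome blocks, as passenger segments from another strain may bring, could give this. The random sets were drawn gene by gene, however, so members of a family that lie side by side can exceed them without such blocks. The 18 include the T cell receptor segments Trbv23 and Trbv26 on chromosome 6 and the genes counted on Y. Without genes of a shared symbol stem, pseudogenes and clone-named models, 2 of 29 had a neighbour, as did at least as many in 3676 of 10000 random sets. Genes were left out by name and not by sequence, which on chromosome 11 also took out BC018473 and St6galnac2. The test therefore cannot tell reads shared between paralogs from blocks, with too few genes left to decide. Cygb and Mxra7, which stayed in, share no stem. Cygb had 107 wild-type and 4 ko counts at 48 h, and 33 and 0 at 72 h. Mxra7 had 495 and 103 counts at 48 h, and 859 and 209 at 72 h. Unlike symbols do not test whether either gene shares reads with copies elsewhere, so this pair does not decide between the explanations. The biological explanation, an effect of Batf3 itself on each gene, was not tested.

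At 72 h 5526 genes passed, most by less than 2-fold. A trend with transcript length may add to them, but 4277 of the 5526 genes called stayed called in the same direction once each library's trend with exon length was removed (77.4%), which argues against it as the whole cause. The libraries farthest out on the main axis of variation within groups were replicate 4 of the ko cells at 48 h (0.558) and replicate 4 of the wild type at 72 h (-0.512). Without both, 5222 stayed called (94.5%), which argues against the wild-type library as the whole cause. The ko library is from 48 h and enters the 72 h comparison only through the scaling and the shared estimate of the spread. A difference between cultures or animals stays open, because the replicates are technical, and so does the genotype.

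Granule genes were higher in ko cells at both times. Of the 13 granule genes called higher at 72 h, 12 stayed higher with exon length offsets, which argues against transcript length as the whole cause. More NK or gamma delta T cells in the ko cultures might raise them. The median of the 12 markers of those cells at 72 h was 0.387 (95% bootstrap interval 0.161 to 0.947). That interval holds the median of the granule genes called higher, 0.557, and that of all 21 granule genes, 0.356, so the explanations cannot be told apart with so few markers. Klre1, among these markers, was also among the 55 genes at least 2-fold apart in the same direction at both times (1.02 and 1.03). It had no such neighbour within 0.5 Mb, but a sequence difference carried with the ko allele was not excluded for it. Activated CD8 T cells can express some of these markers too, and an effect of the genotype on the CD8 T cells stays open as the biological explanation.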
